A study of Mus musculus with 32 samples.

How the data were processed

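The series was read from 8 deposited tables with values for 32 samples, 24 RNA-seq libraries and 8 ChIP-seq or input libraries. Per the submitters' processing notes, STAR 2.4.0, RSEM 1.2.25, Bowtie 1.1.1, bcl2fastq 1.8.4 and HOMER (its version was not given in the sources used here) were used with the mouse build mm10. Per the file headers, the authors made the gene count tables with HOMER, which counted reads in the exons of each RefSeq gene and condensed transcripts to 1 entry per gene symbol, without adjusting for depth. The Phase 1 count table carried the command of its RPKM partner in its header, but held whole numbers. The deposited RPKM values were the same counts scaled by exon length and library size, per the file headers. Within each library, log2 RPKM and log2 counts of genes with at least 200 counts in every library of the table differed by a standard deviation of 0.01 to 0.016 after centring each gene, so both tables held the same libraries in the same columns. Counting was by exon and gene symbol and no strand setting was given in the sources used here. Reads of overlapping or antisense genes therefore could not be separated, and members of families with near-identical copies, such as the globins, granzymes and interferon-induced genes, were treated as uncertain in their exact share of reads.

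The peak lists were the authors' own, with 1 list per phase, so replicates could not be compared at single peaks. The deposited names refer to reproducibility between replicates (irreproducible discovery rate), and how the replicates were combined was otherwise not given in the sources used here. Per the file headers, each peak carried a normalized tag count, which is a signal scaled by HOMER to a fixed total, and a total tag count without scaling. The same deposited headers gave the fraction of tags near the peak centre (focus ratio), the HOMER score, the fold over control as a ratio, and a p-value against control. These values were used only to describe, rank or halve the peaks within a list. The lowest fold over control in both lists was 4.0, taken as the lower limit of the deposited calls.

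Genes were tested on the deposited counts with edgeR's quasi-likelihood test (glmQLFit with robust moderation and glmQLFTest), after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and log2 fold changes are given with their standard error (SE). Each of the 3 count tables was fitted on its own with all its groups in 1 model, which tested 14245 genes in the developmental stage table, 13719 in Phase 1 and 13465 in Phase 2. The common biological coefficient of variation was 0.133, 0.274 and 0.232 in the same order. One further fit joined the perturbation tables of both phases (14315 genes) and tested whether the change against the control of the same phase differed between phases. TMM factors lay between 0.949 and 1.026, and scaling by the median ratio of DESeq2 in its place moved the median gene by at most 0.022 log2. Levels are CPM on the TMM-scaled library size (mean ± SD). Where every library of a group had 0 counts, the fold was computed against a floor of 3 counts over the group and is written as at least that fold. Where a group had 1 to 3 counts, CPM levels are given without a fold. The intervals and floors cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules.

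Gene lists were fixed before the data were examined and covered stem and progenitor genes, T-cell identity genes, Notch targets, myeloid genes, B-cell and dendritic-cell genes, NK and innate lymphoid genes, γδ and type 17 T-cell genes, Runx family and cofactor genes, cell-cycle genes, p53 targets, interferon-induced genes, migration genes, erythroid, megakaryocyte and mast-cell genes, genes of the feeder stroma, immediate early genes of tissue dissociation, and mitochondrially encoded genes. None of the 11 mitochondrially encoded genes was among the genes of the tables, so that list gave no result. Each list was tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 15 lists of a comparison. It was tested again with an estimated correlation, and with fry. The counts within a list are given over all genes tested and again adjusted over the list alone. With an estimated correlation, 2 of 225 list tests stayed under 0.05, against 92 with the preset value. They were the T-cell identity list between the 2 single targets in Phase 1 and the same list in the test between phases. Stage lists were the genes called higher in DN2a or in ETP cells of this series. They come from other libraries of the same study and are not independent evidence of direction.

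Peaks of both phases were called shared when they overlapped by at least 1 bp (bedtools), and phase-only otherwise. A peak centre within 1000 bp of a transcription start was called promoter. Each peak was assigned to the gene with the nearest start within 100 kb, using the gene positions in the deposited count tables (mm10). Of 23254 gene symbols on the same chromosome in the RefSeq gene table, 79.2% had the same start or end there, and 14 peaks lay on a contig without a gene. Peak classes and called genes were compared with Fisher's exact test, two-sided, with 95% intervals of the odds ratio. Benjamini-Hochberg adjustment ran over the 12 combinations of perturbation, direction and peak class, and the tests were repeated within deciles of mean expression by the Cochran-Mantel-Haenszel test.

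The library numbers printed in the deposited headers fell into separate series: 2 in Phase 1, 3 in Phase 2 and 1 in the stage table. In Phase 1 the series equalled the replicate number of each group. In Phase 2 it did so except that double-target replicate 2 belonged to series 3. Deviations from the group mean showed this grouping across genes. In Phase 2, the 9 same-numbered pairs among control and single-target libraries correlated at 0.59 to 0.91. Double-target replicate 2 correlated at −0.77 to −0.58 with the libraries of its number and at 0.68 to 0.86 with those of its series. In Phase 1 the pairs correlated at 0.91 to 0.93, and at 0.54 to 0.63 where the double target was a member. Library series was therefore added as a term in an alternative fit, chosen after the data were seen. Its values stand beside the counts of perturbation calls and some list and gene results. The labels did not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

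The genes named in the text followed a rule fixed before the data were examined. It took Runx1 and Runx3 in every perturbation library, and Il2ra, Kit and Bcl11b in every stage library. For each main comparison it took the 5 called genes with the highest and the 5 with the lowest log2 fold change among those with a mean of at least 5 CPM in the higher group, leaving out unnamed gene models. For the comparisons between perturbations it took 3 each way. From each list it took up to 4 called members with the smallest adjusted p, and up to 2 members that were not called where fewer than 2 were. For peaks it took 20 loci of T-cell and progenitor genes, with the strongest peak of each class, and the 3 strongest phase-only peaks of each phase. One gene of these is not reported here. The comparisons, tests and alternatives named as planned were also fixed beforehand.

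Alternatives recomputed the gene tests with DESeq2, with DESeq2 size factors, without a filter on low counts, with a stricter filter (1 CPM in every library of a group), and with a log2 fold change of at least 1 added to the threshold. Further ones used the replicate number as a block, left out each library in turn, fitted only the groups compared, or ran limma-trend on log2 of the deposited RPKM plus 0.1 or plus 1 for genes with a mean RPKM over 0.5. The last 2 were not run for the difference between phases, and its single-target tests were repeated only with library series. The stage comparison was repeated with groups by the cell surface gate in the labels, not by the titles. For peaks they changed the overlap rule, promoter width, assignment distance and peak strength.

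Each test was first run on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed by known amounts, 100 at log2 1 and 100 at log2 2. For DN2a against ETP, 84% of the genes changed by log2 1 and 96% of those by log2 2 were called. The same shares were 23% and 87% for sgRunx1 and 35% and 92% for the double target in Phase 1. In Phase 2 they were 64% and 98% for sgRunx1, 75% and 97% for sgRunx3 and 55% and 96% for the double target. False calls numbered 43 for DN2a against ETP, well above the nominal share, and 4 to 11 elsewhere. Of 3406 simulated peaks, 100% went to their true gene and all 2037 shared ones were found, a check of the code only.

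The computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.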

Results

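The series followed mouse bone marrow progenitors that entered the T-cell path in culture, on OP9-DLL1 cells, a stromal feeder line that carries the Notch ligand DLL1, with IL-7 and Flt3 ligand. RNA-seq and Runx3 ChIP-seq were made to ask what the transcription factors Runx1 and Runx3 do before (Phase 1) and after (Phase 2) commitment to the T-cell fate. RNA-seq of unperturbed stages used mice with a fluorescent Bcl11b reporter. Early T-cell precursors (ETP) were taken on day 4 (2 libraries), and DN2a cells on day 6, as Bcl11b-negative (2 libraries) and Bcl11b-positive cells (1 library). For the perturbations, cells expressing Cas9 and Bcl2 received guide RNAs by retrovirus on day 2 (Phase 1) or day 10 (Phase 2), with 3 guides per target, and were sorted 3 days later. The sort took lineage-negative infected cells with high cKit in Phase 1 and with CD25 in Phase 2. Guides against Runx1 (sgRunx1), Runx3 (sgRunx3) or both (double target) were compared with control guides. Phase 1 held 2 libraries per group, and Phase 2 held 3 per group except for 2 double-target libraries. Runx3 ChIP-seq was made on cKit-high CD25-negative cells of day 5 (Phase 1) and cKit-low CD25-positive cells of day 10 (Phase 2), with 2 ChIP and 2 input (1%) samples in each phase.

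Each count table held 24506 genes, and the total counts of the 24 RNA-seq libraries lay between 21969031 and 32560595. The ETP libraries held 27083982 and 30981544 counts, the Bcl11b-negative DN2a libraries 24549543 and 28403790, and the Bcl11b-positive library 25687285. Control, sgRunx1, sgRunx3 and double-target libraries of Phase 1 held 25156823 and 29104440, 25846907 and 25084366, 24323788 and 28310355, and 26284290 and 23110351 counts. In Phase 2 they held 23171207, 24000633 and 29624027, 23985126, 21969031 and 32560595, 24040187, 23725265 and 29243891, and 23586669 and 30950599 counts in the same order. The titles and the cell surface gates in the labels contradicted each other for ETP replicate 2 and for Bcl11b-negative DN2a replicate 1, and the titles were used.

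Il2ra encodes CD25, the marker of the step from ETP to DN2a (NM_008367, chromosome 2, 11642792 to 11693194, plus strand, mm10). Its level was 35.1 and 38.6 CPM in the ETP libraries, 1850 and 2700 CPM in Bcl11b-negative DN2a and 2710 CPM in Bcl11b-positive DN2a. Both libraries with contradictory labels thus carried the Il2ra level of their titles. Bcl11b, a transcription factor of T-cell commitment (NM_001079883, chromosome 12, 107910403 to 108003414, minus strand), lay at 0.146 and 0.672 CPM in ETP, 4.09 and 13 CPM in Bcl11b-negative DN2a and 234 CPM in the Bcl11b-positive library. Kit, the receptor of stem cell factor (NM_001122733, chromosome 5, 75574987 to 75656721, plus strand), lay at 396 and 398, at 473 and 432, and at 216 CPM in the same order.

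**Figure D1:**
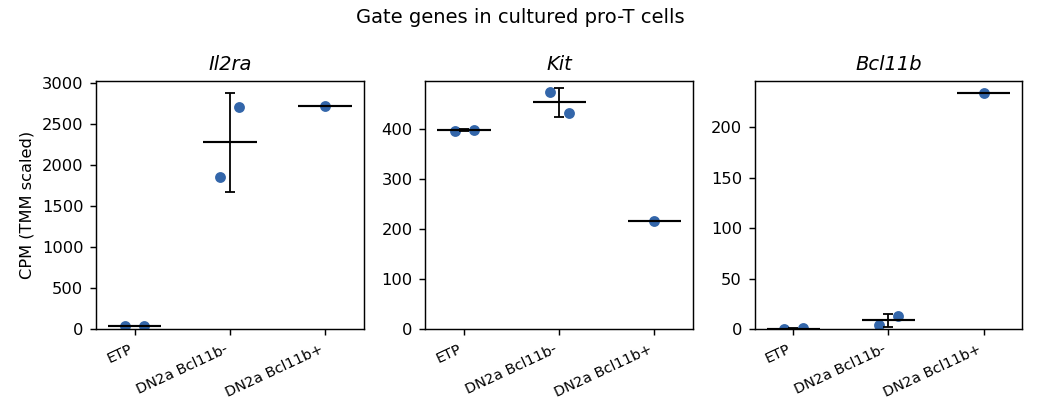
CPM (vertical axes) of Il2ra, Kit and Bcl11b in each ETP, Bcl11b-negative DN2a and Bcl11b-positive DN2a library (points), with the mean (line) and SD (bar) where there were 2 libraries. Il2ra stayed at 38.6 CPM or less in ETP and reached at least 1850 CPM in every DN2a library.

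From ETP to Bcl11b-negative DN2a, most progenitor, myeloid and B-lineage genes of the fixed lists fell, and 12 of 25 T-cell identity genes rose. Il2ra rose by log2 5.98 ± 0.29 (SE, adjusted p 0.00422), from 36.8 ± 2.52 to 2270 ± 604 CPM (SD, n = 2 each), and Tcf7, which encodes the T-cell factor TCF1, rose by 2.32 ± 0.08 (adjusted p 3.72e-05), from 206 ± 17.6 to 1000 ± 53.1 CPM. Flt3, the receptor of Flt3 ligand on progenitors, fell by log2 5.95 ± 0.18 (adjusted p 3.47e-05), from 73 ± 12.9 to 1.15 ± 0.0441 CPM. Csf1r, the macrophage growth factor receptor (NM_001037859, chromosome 18, 61105572 to 61131139, plus strand), fell from 203 ± 1.34 to 8.35 ± 1.17 CPM (log2 −4.57 ± 0.11, adjusted p 2.07e-05). In all, 1859 of 14245 genes were higher and 1747 lower in DN2a, and 276 and 794 of them changed at least 2-fold. Besides Il2ra, the granzyme Gzma (4.74 ± 0.52, adjusted p 0.0313), Podxl (4.44 ± 0.31), Fam20a (4.21 ± 0.19) and the adhesion molecule Epcam (4.21 ± 0.19) rose most among genes of at least 5 CPM. The lowest changes were those of the basophil and mast-cell protease Prss34 (−9.1 ± 0.31, adjusted p 0.000747; 259 ± 1.65 CPM in ETP) and of 4 genes at or near 0 in DN2a. Fcrla (6.24 CPM in ETP) was at least 107-fold lower and the IgE receptor subunit Fcer1a (5.5 CPM) at least 94.5-fold lower. Cplx2 (23 CPM in ETP) had 1 count and Ms4a2 (27.6 CPM), another subunit of that receptor, 2 counts over both DN2a libraries.

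The count of calls was 1491 to 2609 without 1 of its libraries, and grouping by the gate in the labels gave 0 calls.

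By list, 3 of 20 progenitor genes rose, 13 fell and 4 were not called in DN2a (3 and 14 adjusted over the list alone, median log2 −1.63; camera adjusted p 9.1e-11). Lmo2, a cofactor of stem-cell transcription factors, fell (log2 −3.43 ± 0.1), and Spi1, which encodes the myeloid and progenitor factor PU.1, fell by 1.15 ± 0.08, from 165 ± 12.4 to 72.8 ± 2.57 CPM. Of 25 T-cell identity genes, 12 rose, 2 fell and 11 were not called (13 and 2 in the list alone, median 1.32; camera adjusted p 3.17e-09). The kinase Lck rose by 1.03 ± 0.08, whereas Cd6 fell by 1.27 ± 0.14. Of 11 Notch targets, 2 rose (Il2ra and Tcf7, which also stand in the T-cell list) and 9 were not called (2 in the list alone, median 0.22; camera adjusted p 0.0035).

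Of 20 myeloid genes, 13 fell, 1 rose and 6 were not called (2 higher and 16 lower adjusted over the list alone, median −2.95; camera adjusted p 2.61e-14), with Itgam at −3.99 ± 0.11 and Csf2rb at −2.59 ± 0.12. Of 19 B-cell and dendritic-cell genes, 13 fell and 6 were not called (1 higher and 15 lower in the list alone, median −3.91; camera adjusted p 4.05e-13), and the B-lineage genes Pax5 (10.1 CPM in ETP) and Blnk (14 CPM) had 2 counts each over both DN2a libraries. Of 14 erythroid, megakaryocyte and mast-cell genes tested, 2 rose and 6 fell (2 and 7 in the list alone, median −2.55; camera adjusted p 0.00285). The basophil protease Mcpt8 fell by log2 3.3 ± 0.17, from 241 ± 8.47 to 23.9 ± 5.59 CPM, and the megakaryocyte integrin Itga2b rose by 2.09 ± 0.14. Of 22 NK and innate lymphoid genes, 4 rose, 1 fell and 17 were not called (4 and 1 in the list alone, median 0.36; camera adjusted p 0.00401), with Zbtb16, the factor of innate-like lymphocytes, at 3.38 ± 0.35 and Cd160 at 2.28 ± 0.11. Estimating the correlation gave these 7 lists adjusted p-values of 0.516 to 0.52.

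The remaining lists gave no call by camera at adjusted p under 0.05. Higher and lower genes numbered 0 and 2 of 11 γδ and type 17 genes, 1 and 2 of 9 Runx family and cofactor genes, 3 and 1 of 19 cell-cycle genes, and 3 and 3 of 15 p53 targets. They numbered 0 and 0 of 16 interferon-induced genes, 1 and 4 of 10 migration genes, 1 and 1 of 13 stromal genes, and 2 and 3 of 12 dissociation genes. Adjusted over the list alone, these counts changed only for cell-cycle (4 and 2) and dissociation genes (2 and 4). Runx2 fell by log2 1.33 ± 0.1 (adjusted p 0.000596), and the chemokine receptors Ccr4 and Ccr7 changed by 3.44 ± 0.2 and −2.24 ± 0.26. Kit rose by 0.22 ± 0.06 (adjusted p 0.0492), and Bcl11b was not called (4.36 ± 1.24, adjusted p 0.145).

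The Bcl11b-positive library was compared with the 2 Bcl11b-negative DN2a libraries, with the spread taken from the replicated groups and the lone library assumed to vary like them. A feature of that 1 library cannot be told from the stage. Dntt, the terminal transferase of antigen receptor rearrangement (NM_009345, chromosome 19, 41029275 to 41059525, plus strand), stood at 731 CPM against 18.5 ± 6.41 CPM (log2 5.28 ± 0.48, adjusted p 0.0202). Spi1 stood at 14.1 CPM against 72.8 ± 2.57 CPM (−2.39 ± 0.11, adjusted p 0.000256). In all, 1869 genes were higher and 2059 lower. Leaving out DN2a replicate 1 or 2 gave 1738 or 2184 calls. Pdlim4 (6.7 ± 0.44), Gprin3 (4.92 ± 0.37), Il13 (4.75 ± 0.78) and Spib (4.45 ± 0.63) were the other genes with the largest increases. Adgrl4 (−5.35 ± 0.32), Tnni1 (−4.96 ± 0.61), Sh2d1b1 (−4.47 ± 0.33), P2rx1 (−4.17 ± 0.26) and Csf1r (−4.07 ± 0.22) had the largest decreases. Bcl11b itself stood at log2 4.74 ± 0.88 with an adjusted p of 0.0721, and Kit fell by 1.09 ± 0.08.

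Of 25 T-cell identity genes, 13 were higher in the Bcl11b-positive library and 12 were not called (18 higher adjusted over the list alone, median 1.95; camera adjusted p 3.87e-12). They included Ptcra, the pre-T-cell receptor α chain (4.03 ± 0.59), Rag2 (1.95 ± 0.16) and Cd247 (2.5 ± 0.22). Of 20 progenitor genes, 1 was higher, 11 lower and 8 not called (2 and 11 in the list alone, median −0.99; camera adjusted p 1.49e-15), among them Mycn (−2.57 ± 0.13), Lmo2 (−2.6 ± 0.17) and Bcl11a (−2 ± 0.12). Of 20 myeloid genes, 1 was higher, 8 lower and 11 not called (1 and 8 in the list alone, median −0.97; camera adjusted p 1.94e-08). Of 13 stromal genes, 6 were higher (7 in the list alone, median 2.38; camera adjusted p 2.81e-07), such as Postn at 13 against 2.12 CPM, and β-globin Hbb-b1 lay at 42.6 against 407 ± 104 CPM.

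Notch targets in the same comparison held 4 higher and 2 lower of 11 genes (5 and 2 adjusted over the list alone), with Notch3 at log2 2.28 ± 0.11 and the feedback inhibitor Nrarp at −0.9. Migration genes held 6 higher and 1 lower of 10 (7 and 1 in the list alone; camera adjusted p 0.0254). Erythroid, megakaryocyte and mast-cell genes held 1 higher and 4 lower of 14 (2 and 4 in the list alone), with a median of 0, a mean of −0.17 and a camera adjusted p of 0.009 towards lower values. The NK and innate lymphoid list had a median of 0.17 and a mean of −0.33 (camera adjusted p 0.211). Ncr1 (1.07 CPM in the Bcl11b-negative libraries) was at least 9.25-fold lower. Interferon-induced genes held 0 calls among 16, and Runx1 was higher by 0.57 ± 0.09 (adjusted p 0.00606). The lists called by camera had adjusted p-values of 0.338 to 0.588 with an estimated correlation.

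For the perturbations, the mRNA of the targeted genes was measured first in every library. A guide can disable a gene without lowering its mRNA, so these levels did not check whether the guides worked. Runx1 (NM_001111021, chromosome 16, 92601466 to 92826074, minus strand, mm10) lay at 172 and 180 CPM in Phase 1 controls, 245 and 235 with sgRunx1, 220 and 217 with sgRunx3, and 320 and 314 with the double target. In Phase 2 it lay at 321, 390 and 309 CPM in controls, 620, 646 and 484 with sgRunx1, 330, 402 and 332 with sgRunx3, and 677 and 622 with the double target. Runx3 (NM_019732, chromosome 4, 135120645 to 135177990, plus strand) lay at 149 and 188, 159 and 187, 134 and 175, and 120 and 152 CPM in Phase 1 in the same order of groups. In Phase 2 it lay at 187, 215 and 209 in controls, 209, 220 and 233 with sgRunx1, 156, 172 and 171 with sgRunx3, and 232 and 223 with the double target.

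Runx1 mRNA rose by log2 0.86 ± 0.1 in the Phase 1 double target (adjusted p 0.0172), 0.78 ± 0.15 with sgRunx1 in Phase 2 (adjusted p 0.0268) and 0.94 ± 0.16 in the Phase 2 double target (adjusted p 0.00802). With sgRunx1 in Phase 1 its value was 0.44 ± 0.09 (adjusted p 1, and 0.139 with library series as a term). Runx3 mRNA was not called in any comparison with control without the series term. It stood at −0.12 ± 0.2 with sgRunx3 in Phase 1, −0.29 ± 0.09 with sgRunx3 in Phase 2, and −0.3 ± 0.2 in the Phase 1 double target (adjusted p 0.508, and 0.0333 with library series as a term). Runx3 was higher in the Phase 2 double target than with sgRunx3 there (0.47 ± 0.11, adjusted p 0.0363).

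**Figure D2:**
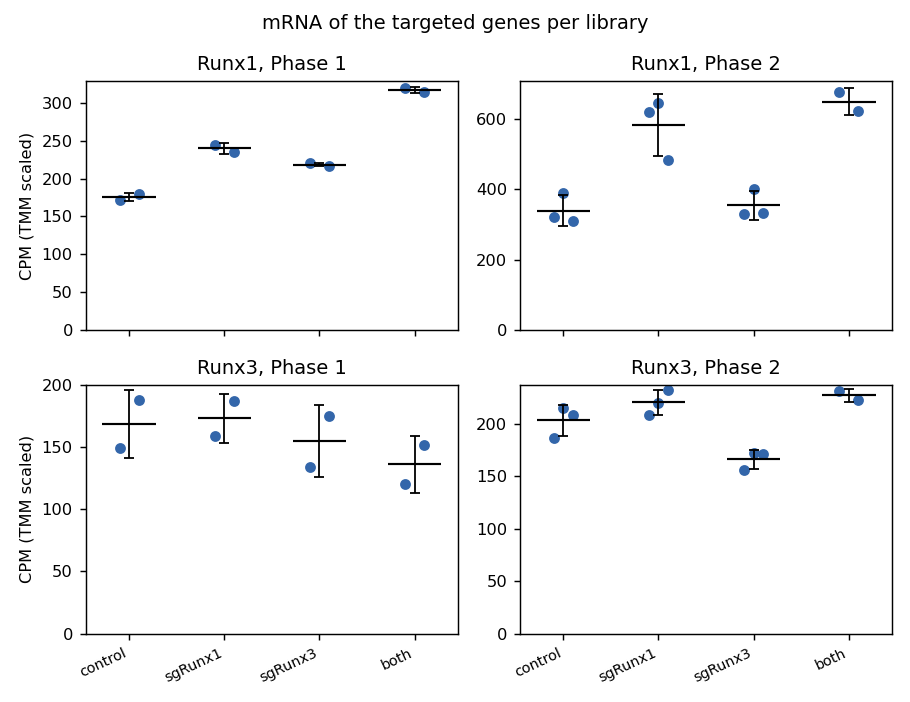
CPM (vertical axes) of Runx1 and Runx3 in each perturbation library of both phases (points), with group means (lines) and SD (bars), for control guides, sgRunx1, sgRunx3 and both targets. Runx1 mRNA was higher in libraries with Runx1 guides, at 484 to 677 CPM in Phase 2 against 309 to 390 CPM in controls.

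In Phase 1, a single target gave no called gene against control guides. With edgeR, sgRunx1 and sgRunx3 each gave 0 calls among 13719 genes, with 330 and 232 genes at an unadjusted p under 0.05, and DESeq2 called 33 and 4. The T-cell receptor component Cd3g (NM_009850, chromosome 9, 44969572 to 44980431, minus strand) stood at 7.03 ± 0.056 CPM with sgRunx1 against 23.8 ± 4.48 CPM in controls (log2 −1.76 ± 0.2, adjusted p 0.907). With sgRunx3, Thy1 stood at 252 ± 2.96 against 152 ± 22.5 CPM (0.73 ± 0.19) and the CD103 integrin gene Itgae at −1.38 ± 0.35, both at an adjusted p of 1. Library series as a term left both counts at 0. Leaving the double-target libraries out of the fit and adding that term gave 556 higher and 564 lower genes for sgRunx1, and 388 and 375 for sgRunx3.

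The lists held no called gene for either single target in Phase 1. Adjusted over the list alone, sgRunx1 had 1 lower T-cell identity gene, 1 higher and 1 lower progenitor gene, and Runx1 in the Runx list, while sgRunx3 had 1 higher NK and innate lymphoid gene and 1 lower γδ and type 17 gene. With library series as a term, that adjustment gave 11 higher interferon-induced, 6 lower B-cell and dendritic-cell and 5 lower T-cell identity genes with sgRunx1, and 2 higher T-cell identity, 2 higher NK and innate lymphoid and 3 higher and 2 lower γδ and type 17 genes with sgRunx3, and up to 2 each way in other lists. By camera with sgRunx1, interferon-induced genes lay higher (median log2 0.6, adjusted p 1.03e-14), and B-cell and dendritic-cell genes (−0.95, 8.39e-13), stromal genes (−1.07, 4.26e-07) and T-cell identity genes (−0.2, 0.00137) lay lower. With sgRunx3, T-cell identity genes lay higher (0.32, adjusted p 6.25e-07), and stromal genes (−0.32, 0.0265) and B-cell and dendritic-cell genes (−0.34, 0.00452) lower. With an estimated correlation, these adjusted p-values were 0.161 to 0.66. With library series as a term, camera also called Notch targets (adjusted p 0.0438) and γδ and type 17 genes (0.00974) lower with sgRunx1, and NK and innate lymphoid genes (0.00983) and erythroid, megakaryocyte and mast-cell genes (0.00829) higher with sgRunx3.

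Between the single targets, T-cell identity genes lay lower with sgRunx1 than with sgRunx3 in Phase 1 (median log2 −0.43, camera adjusted p 6.23e-20, and adjusted p = 0.0421 with an estimated correlation). Stromal genes (−0.66, 0.00308), B-cell and dendritic-cell genes (−0.48, 1.97e-06), NK and innate lymphoid genes (−0.24, 0.00386), γδ and type 17 genes (−0.44, 0.0069) and Notch targets (−0.19, 0.0144) lay lower there too. No single gene was called by edgeR, 210 genes had an unadjusted p under 0.05, DESeq2 called 5, and 4 T-cell identity genes were lower adjusted over the list alone. Library series as a term left the count at 0 and gave 8 lower T-cell identity, 6 lower NK and innate lymphoid, 3 lower γδ and type 17, 3 lower erythroid, megakaryocyte and mast-cell and 11 higher interferon-induced genes in the list alone, and 651 genes in all without the double-target libraries. Interferon-induced genes (median 0.5, camera adjusted p 7.07e-16) and progenitor genes (0.16, 0.0311) lay higher with sgRunx1. Lists other than the T-cell one had adjusted p-values of 0.134 to 0.487 with an estimated correlation.

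In the Phase 1 double target, 4 T-cell identity genes fell and 3 progenitor genes rose. Cd3g fell to 2.01 ± 0.112 CPM from 23.8 ± 4.48 CPM (log2 −3.56 ± 0.22, adjusted p 0.0113, n = 2 each). Lck (NM_010693, chromosome 4, 129548344 to 129558372, minus strand) fell to 25.6 ± 6.52 from 170 ± 53.3 CPM (−2.72 ± 0.37, adjusted p 0.0289). Meis1, a homeobox factor of stem cells (NM_001193271, chromosome 11, 18880428 to 19018969, minus strand), rose to 47.2 ± 1.2 from 13.5 ± 3.56 CPM (1.81 ± 0.22, adjusted p 0.0205). Tal1, a factor of blood stem and erythroid cells (NM_011527, chromosome 4, 115056426 to 115071755, plus strand), rose to 68.7 ± 32.6 from 15.3 ± 2.92 CPM (2.18 ± 0.36, adjusted p 0.0454). In all, 175 of 13719 genes rose and 106 fell. The largest increases were those of Treml1, a platelet receptor (6.54 ± 0.55, adjusted p 0.0115), Mylk3 (6.33 ± 0.52), the erythroid gene Rhag (6.12 ± 0.88), the 12-lipoxygenase gene Alox12 (8.57 ± 7.66 CPM against 0.0541 ± 0.0193 CPM from 3 counts) and Hap1 (5.97 ± 0.357 CPM against 0.0371 ± 0.00463 CPM from 2 counts). The largest decreases were those of Pkd2l1 (−4.43 ± 0.42), Gpr25 (−3.58 ± 0.43), Cd3g, Tmem121 (−3.32 ± 0.43) and the kinase Blk (−3.29 ± 0.26).

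The count of the Phase 1 double target depended on single libraries and on the fit. It was 0 without control replicate 1 or 2, 47 without double-target replicate 1, 1158 without double-target replicate 2 and 0 with only the 2 groups fitted, whereas library series as a term gave 1466 higher and 1012 lower genes.

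By list, 4 of 24 T-cell identity genes fell in the Phase 1 double target and 20 were not called (1 higher and 12 lower adjusted over the list alone, median log2 −0.9; camera adjusted p 3.69e-08). The 4 were Cd3g, Lck, Cd5 (−1.66 ± 0.23) and Thy1 (−1.24 ± 0.19). Tcf7 stood at 89.1 ± 29.7 against 457 ± 161 CPM (−2.35 ± 0.44, adjusted p 0.0568, and 0.00055 with library series as a term), and Il2ra at −1.63 ± 0.47 (adjusted p 0.149, and 0.00376 with series). Of 20 progenitor genes, 3 rose and 17 were not called (4 higher and 2 lower in the list alone, median 0.14; camera adjusted p 0.0863, and 0.0292 with series). Of 15 erythroid, megakaryocyte and mast-cell genes, the carbonic anhydrase gene Car2 rose (2.28 ± 0.31) and 14 were not called (7 higher in the list alone, median 1.92; camera adjusted p 1.83e-05). Of 8 γδ and type 17 genes, 2 fell (3 in the list alone, median −1.2; camera adjusted p 0.000273), Blk and Cd163l1 (−2.34 ± 0.24). In the NK and innate lymphoid list, Id2, which encodes an inhibitor of E proteins, rose (1.23 ± 0.19, adjusted p 0.0377), Gzma fell (−2.76 ± 0.36) and 20 were not called (2 and 2 in the list alone).

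Interferon-induced genes held 4 higher genes among 16 (10 adjusted over the list alone, median 1.1; camera adjusted p 1.09e-10), such as Ifit1 (2.26 ± 0.31) and Irf7 (1.15 ± 0.19). Stromal genes held 0 calls among 12 and 8 lower genes in the list alone (median −2.21, camera adjusted p 1.29e-06). Pdgfrb of that list stood at 24.5 ± 6.46 against 114 ± 40.8 CPM (−2.22 ± 0.47, adjusted p 0.0762). Col1a1 lay at only 11.3 and 7.62 CPM in the same controls, and Pdgfrb at 169 and 204 CPM in the ETP libraries. Pdgfrb was therefore not taken as a marker of feeder cells. Myeloid genes held 0 calls among 20 (1 higher in the list alone, median 0.49; camera adjusted p 0.0119). Notch targets held 0 calls among 10 (1 lower in the list alone, median −0.9; camera adjusted p 0.0119). B-cell and dendritic-cell genes held 1 lower gene among 18, Ly6d (−2.47 ± 0.4), also in the list alone (median −0.83; camera adjusted p 0.00089). Cell-cycle genes held 0 calls among 19, also in the list alone (median −0.28; camera adjusted p 0.00089).

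Of 15 p53 targets, 1 rose in the Phase 1 double target, Eda2r (3.93 ± 0.65), and 2 were higher adjusted over the list alone (median 0.62; camera adjusted p 0.00356). Of 9 Runx list genes, Runx1 rose (1 higher and 2 lower in the list alone). Migration genes had a median of −0.33 and a mean of 0.11 with 1 higher gene of 10, S1pr1 (3.12 ± 0.36; 1 higher and 1 lower in the list alone). Dissociation genes had 0 calls among 12 (2 higher in the list alone, median 0.46; camera adjusted p 0.241, and 0.0349 with series). With library series as a term, 1 T-cell identity gene was higher and 14 lower, and higher genes numbered 5 of the progenitor, 9 of the erythroid, megakaryocyte and mast-cell, 15 of the interferon-induced and 8 of the myeloid genes. Lower genes numbered 8 stromal genes, 5 Notch targets and 4 γδ and type 17 genes in that fit. All lists called by camera without series had adjusted p-values of 0.281 to 0.573 with an estimated correlation.

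**Figure D3:**
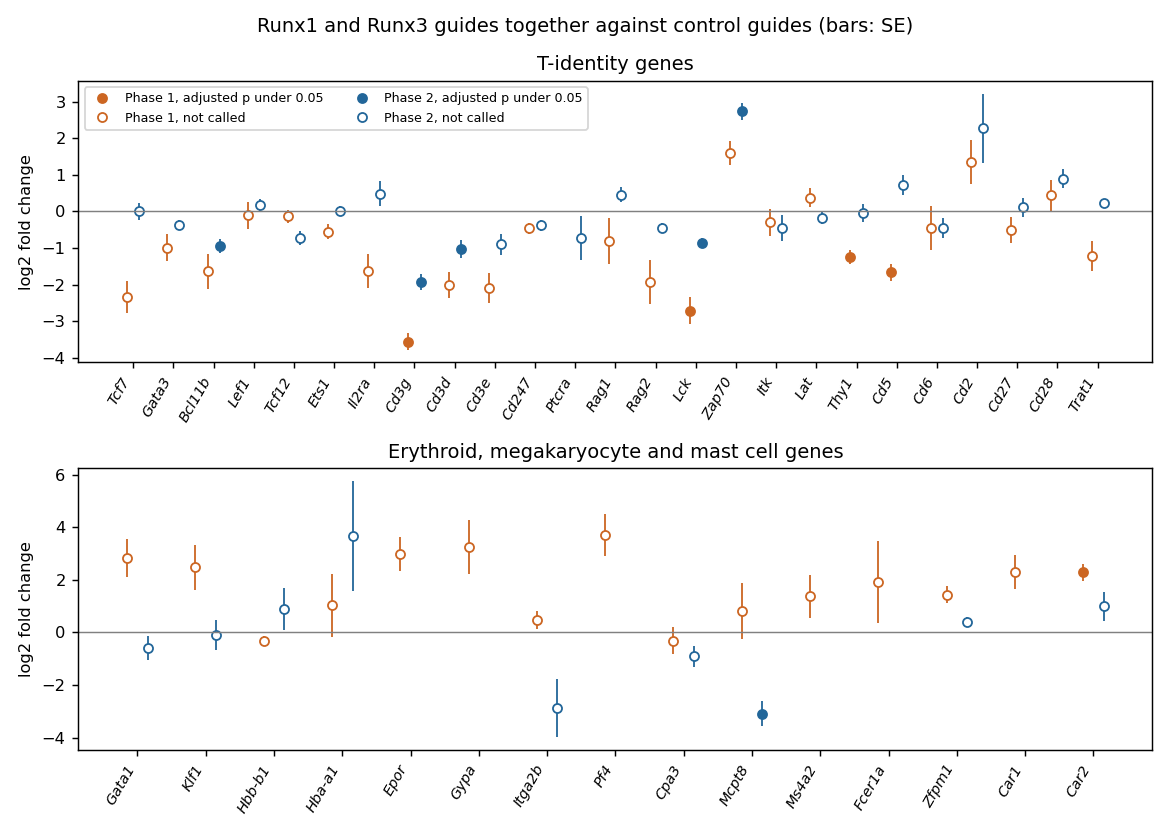
Log2 fold change (vertical axes, bars SE) of T-cell identity genes and of erythroid, megakaryocyte and mast-cell genes (horizontal axes) in the double target against control, in Phase 1 and Phase 2. Filled points passed an adjusted p of 0.05; the median of the T-cell list was −0.9 in Phase 1 and −0.17 in Phase 2, and that of the other list 1.92 and −0.1.

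Against sgRunx3, the Phase 1 double target had 41 genes higher and 36 lower. Treml1 (log2 5.14 ± 0.5), Mylk3 (4.67 ± 0.46) and the growth factor Pdgfb (7.52 ± 3.29 CPM in the double target, 3 counts over both sgRunx3 libraries) were higher, and Epcam (−3.85 ± 0.23), Cd3g (−3.53 ± 0.22) and Gzma (−3.32 ± 0.37) were lower. Of the T-cell identity genes, 2 were lower, and 15 adjusted over the list alone (median −1.09; camera adjusted p 3.21e-16; adjusted p = 0.067 with an estimated correlation, and 0.0401 with series), and stromal genes lay lower too (−1.94, 7 lower in the list alone; camera adjusted p 1.57e-05, and 0.201 with an estimated correlation). Camera also called progenitor, myeloid, p53, interferon-induced and erythroid, megakaryocyte and mast-cell genes higher and Notch, B-cell and dendritic-cell, γδ and type 17 and cell-cycle genes lower (adjusted p 4.66e-12 to 0.0271). Estimating the correlation gave these 0.189 to 0.549. The count was 0 without sgRunx3 replicate 1 or 2 or double-target replicate 1, 903 without double-target replicate 2, 0 with only these groups fitted and 1935 with series. Against sgRunx1, edgeR called 0 genes, with 1467 at an unadjusted p under 0.05, 406 by DESeq2, 590 without double-target replicate 2 and 1187 with series. T-cell identity genes lay lower there (median −0.69, 6 lower in the list alone; camera adjusted p 8.29e-08), as did stromal genes (−1.23, camera adjusted p 0.000198), and erythroid, megakaryocyte and mast-cell genes higher (median 1.77, 5 higher in the list alone; camera adjusted p 3.49e-07), at 0.28 to 0.344 with an estimated correlation. Myeloid, p53 and interferon-induced genes were also called higher there and Notch, γδ and type 17 and cell-cycle genes lower (1.75e-05 to 0.0425).

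With sgRunx1 alone in Phase 2, Cd3g and Cd3d of the T-cell receptor complex fell and 3 progenitor genes rose. Cd3g fell to 195 ± 42 from 561 ± 83.6 CPM (log2 −1.52 ± 0.18, adjusted p 0.00268, n = 3 each), and Bcl11b fell to 296 ± 45.5 from 524 ± 81.2 CPM (−0.82 ± 0.16, adjusted p 0.0326). Itgae (NM_008399, chromosome 11, 73090583 to 73147449, plus strand) fell to 17 ± 9.77 from 116 ± 32.7 CPM (−2.78 ± 0.49, adjusted p 0.0202). The tetraspanin gene Cd81 rose to 56.7 ± 1.1 from 8.55 ± 1.16 CPM (2.74 ± 0.13, adjusted p 1.52e-05), and Lyl1, a progenitor factor related to Tal1, rose to 174 ± 8.91 from 69.2 ± 6.41 CPM (1.34 ± 0.12, adjusted p 0.00117). In all, 109 of 13465 genes rose and 140 fell, and 1049 and 942 did so with library series as a term. The count was 98 to 167 without 1 of its libraries and 114 with only these groups fitted. Krt80 (3.36 ± 0.49), Tspan32 (2.91 ± 0.42), the transglutaminase Tgm2 (2.82 ± 0.57) and Cpm (2.58 ± 0.46) also rose most, and Prss30 (−2.89 ± 0.57), Rab11fip4 (−2.76 ± 0.23), Tdrd5 (−2.68 ± 0.25) and Snai3 (−2.3 ± 0.28) fell most.

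Of 18 progenitor genes, 3 rose with sgRunx1 in Phase 2 and 15 were not called (4 higher and 1 lower adjusted over the list alone, median log2 0.4; camera adjusted p 0.00131). They were Lyl1, Gata2 (1.61 ± 0.34) and Flt3 (1.37 ± 0.29). Of 25 T-cell identity genes, 4 fell, 1 rose and 20 were not called (2 higher and 7 lower in the list alone, median −0.27; camera adjusted p 0.00209). Cd3d fell by log2 1.11 ± 0.21, and the member that rose was Zap70, a T-cell receptor kinase (1.72 ± 0.21). Of 18 myeloid genes, 2 rose (3 in the list alone, median 0.56; camera adjusted p 0.00141), Csf2rb (1.6 ± 0.19) and Ctsg (1.07 ± 0.19). Of 9 γδ and type 17 genes, 2 fell, also in the list alone (median −0.31; camera adjusted p 0.000575), Cd163l1 (−1.38 ± 0.19) and Sox5 (−1.27 ± 0.26). Of 9 Runx list genes, Runx1 rose, and the corepressor genes Cbfa2t3 (−0.74 ± 0.13) and Tle4 (−0.55 ± 0.11) fell. Stromal genes held 1 lower gene among 12, Pdgfrb (−0.66 ± 0.1), and 2 in the list alone (median −0.74; camera adjusted p 0.000575, and 0.0938 by camera with series). The other lists had a camera adjusted p of 0.141 or more, with Notch3 (−0.65 ± 0.14) and Itgae as their called genes besides. With series, higher and lower genes numbered 6 and 1 of the progenitor, 6 and 10 of the T-cell identity, 7 and 0 of the myeloid, 0 and 5 of the γδ and type 17, 4 and 2 of the NK and innate lymphoid and 4 and 1 of the migration genes. Camera's calls had adjusted p-values of 0.512 to 0.575 with an estimated correlation.

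With sgRunx3 alone in Phase 2, edgeR called 0 genes, 261 had an unadjusted p under 0.05, DESeq2 called 2, and 7 were higher and 8 lower with library series as a term. Id2 stood at 46.1 ± 15.1 CPM against 27.8 ± 3.36 CPM (log2 0.73 ± 0.22, n = 3 each, adjusted p 1, and 0.0166 with series). Stromal genes lay lower by camera (median −0.73, adjusted p 3.3e-05), as did progenitor genes (−0.2, 0.005), Runx list genes (−0.12, 0.005) and dissociation genes (−0.24, 0.0243). NK and innate lymphoid genes lay higher (0.25, 0.000577), as did cell-cycle genes (0.14, 0.018) and p53 targets (0.08, 0.0269, and 0.112 by camera with series). No gene of any list was called, and adjusted over the list alone 1 p53 target was higher. Estimating the correlation gave 0.274 to 0.715 for these lists.

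In the Phase 2 double target, Cd3g, Lck and Bcl11b fell, and Zap70 and some myeloid and progenitor genes rose. Asb2, a ubiquitin ligase component (NM_023049, chromosome 12, 103321142 to 103356001, minus strand), rose to 26.1 ± 5.46 from 0.199 ± 0.0783 CPM (log2 7.03 ± 0.36, adjusted p 1.54e-05; n = 2 against 3). Cd3g fell to 146 ± 15.7 from 561 ± 83.6 CPM (−1.93 ± 0.21, adjusted p 0.000839), Bcl11b to 271 ± 39 from 524 ± 81.2 CPM (−0.94 ± 0.19, adjusted p 0.0162) and Lck to 375 ± 78.2 from 695 ± 20.6 CPM (−0.87 ± 0.14, adjusted p 0.00522). In all, 393 of 13465 genes rose and 318 fell, and 1940 and 1550 did so with library series as a term. Adamdec1 (8.41 ± 1.03), the granulocyte receptor Csf3r (5.46 ± 0.88) and the macrophage marker Adgre1 (5.45 ± 0.43) rose most besides Asb2, and Cd86, a costimulatory ligand of antigen-presenting cells, stood at 8.78 ± 4.25 CPM against 3 counts over the controls. The lowest changes were those of Rab38 (−3.89 ± 0.69), the inhibitory receptor Havcr2 (−3.46 ± 0.4), Epha2 (−3.08 ± 0.57), Itgae (−2.99 ± 0.58) and Psg17 (−2.83 ± 0.51). Leaving out 1 of its libraries gave 370 to 490 calls, and fitting only these groups gave 359.

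Of 18 progenitor genes, 3 rose, 2 fell and 13 were not called (5 and 2 adjusted over the list alone, median log2 0.26; camera adjusted p 0.0986, and 0.0155 with series), with Lyl1 at 1.43 ± 0.13, Cd34 at 1.8 ± 0.36 and Mycn at −1.87 ± 0.26. Of 25 T-cell identity genes, 1 rose, 4 fell and 20 were not called (2 and 7 in the list alone, median −0.17; camera adjusted p 0.106), and Zap70 again rose, to 45.3 ± 5.66 from 6.86 ± 2.34 CPM (2.74 ± 0.23). Of 11 Notch targets, Nrarp rose to 108 ± 33.3 from 28.9 ± 4.75 CPM (1.91 ± 0.25), Hes1 fell (−0.55 ± 0.13) and 9 were not called (2 and 1 in the list alone). Of 18 myeloid genes, 2 rose (3 higher and 1 lower in the list alone, median 0.82; camera adjusted p 0.0064). Of 9 γδ and type 17 genes, 3 fell (1 higher and 4 lower in the list alone, median −0.3; camera adjusted p 0.00971), Cd163l1 (−1.73 ± 0.23), Blk (−1.6 ± 0.29) and Etv5 (−0.9 ± 0.22). Of 21 NK and innate lymphoid genes, Id2 (1.29 ± 0.25) and the perforin gene Prf1 (2.77 ± 0.52) rose, Gzma (−1.05 ± 0.18) and Nkg7 (−1.18 ± 0.21) fell and 17 were not called (3 and 3 in the list alone).

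Interferon-induced genes held 0 calls among 16 in the Phase 2 double target, also adjusted over the list alone (median 0.89; camera adjusted p 0.00971), and 8 higher and 1 lower with series. Cell-cycle genes held 0 calls among 19, also in the list alone (median −0.22; camera adjusted p 0.0986), and 12 lower with series (camera adjusted p 0.000125). B-cell and dendritic-cell genes had 1 lower gene among 12, Vpreb1 (−2.07 ± 0.47), with a median of 0.35, a mean of 0.27 and a camera test that pointed lower (adjusted p 0.733). The mast-cell protease Mcpt8 (−3.08 ± 0.49) was called alone among 9 erythroid, megakaryocyte and mast-cell genes. Pdgfrb (31.5 ± 2.88 against 104 ± 2.77 CPM) was called alone among 12 genes of the stromal list. Runx1 rose and Cbfa2t3 and Tle4 fell among 9 Runx list genes, Zmat3 rose (0.76 ± 0.16) among 14 p53 targets, and Itgae fell among 10 migration genes. Adjusted over the list alone, the last 3 lists held 1 higher and 2 lower, 2 higher and 1 lower, and 0 higher and 1 lower. With series, higher and lower genes numbered 8 and 2 of the progenitor, 7 and 9 of the T-cell identity, 4 and 2 of the Notch, 11 and 1 of the myeloid, 4 and 3 of the B-cell and dendritic-cell, 7 and 5 of the NK and innate lymphoid, 1 and 5 of the γδ and type 17, 3 and 3 of the erythroid, megakaryocyte and mast-cell, 5 and 1 of the p53, 4 and 2 of the migration and 4 and 1 of the dissociation genes. Camera's calls without series had an adjusted p of 0.826 with an estimated correlation.

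Between the perturbations of Phase 2, the double target differed from sgRunx3 in 344 higher and 209 lower genes and from sgRunx1 in 6 higher and 4 lower genes. Against sgRunx1, Asb2 (log2 3.69 ± 0.29), Rgs1 (2.26 ± 0.29) and Rxra (1.34 ± 0.16) were higher and Serpinb1a (−1.41 ± 0.15), Tspan9 (−1.22 ± 0.16) and Pdgfrb (−1.05 ± 0.12) lower. Interferon-induced genes lay higher (median 0.99, camera adjusted p 8.47e-08) and cell-cycle genes lower (−0.28, 0.000286), as did NK and innate lymphoid genes (−0.39, 0.0378), all at 0.806 with an estimated correlation. The calls against sgRunx1 fell to 0 to 4 without 1 of its libraries and to 0 with only these groups fitted, and numbered 2049 with series. Against sgRunx3, Adamdec1 (7.99 ± 1), Cd86 (6 ± 0.99) and Asb2 (5.74 ± 0.32) were higher and Havcr2 (−3.2 ± 0.39), Epha2 (−2.86 ± 0.57) and Itgae (−2.67 ± 0.57) lower. Camera called progenitor, myeloid and interferon-induced genes higher and NK and innate lymphoid, γδ and type 17 and cell-cycle genes lower there (adjusted p 0.00169 to 0.0484; 0.7 to 0.782 with an estimated correlation). That count was 4350 with series, 243 to 332 without 1 of its libraries and 218 with only these groups fitted.

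With sgRunx1 against sgRunx3 in Phase 2, 60 genes were higher and 62 lower. Tgm2 (log2 3.21 ± 0.58), Ankrd33b (3.16 ± 0.61) and the hypoxia-inducible factor gene Epas1 (83.7 ± 9.77 against 12.3 ± 4.54 CPM) were highest, and Tdrd5 (−2.8 ± 0.25), Rab11fip4 (−2.32 ± 0.22) and Snai3 (−2.14 ± 0.27) lowest. Progenitor genes held 2 higher (6 adjusted over the list alone, median 0.57; camera adjusted p 7.43e-09), and γδ and type 17 genes 2 lower (3 in the list alone, median −0.47; camera adjusted p 2.59e-06), and T-cell identity genes (−0.21, 0.00336) lay lower and myeloid genes (0.6, 8.02e-05) higher, at 0.176 to 0.584 with an estimated correlation. The count was 23 to 80 without 1 of its libraries, 34 with only these groups fitted and 1363 with series.

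The double-target change differed between phases (Phase 2 minus Phase 1) for 54 of 14315 genes, 16 positive and 38 negative. The sort gate differed too (high cKit, then CD25), so it cannot be told apart from phase. T-cell genes that fell in Phase 1 had positive differences: Cd5 (log2 2.35 ± 0.38, adjusted p 0.0207), Lck (1.81 ± 0.34, adjusted p 0.0341) and Cd3g (1.59 ± 0.3, adjusted p 0.0374). Tal1 differed in the other direction (−2.92 ± 0.58, adjusted p 0.0473). The largest positive differences were those of Epas1 (3.31 ± 0.52), Cd5, Rtn4rl1 (2.26 ± 0.29), Arpp21 (2.13 ± 0.38) and Cd52 (2.04 ± 0.35), and the largest negative ones those of Shroom4 (−7.46 ± 1.31), Grb10 (−5.53 ± 0.73), Col18a1 (−4.81 ± 0.82), Rab38 (−4.77 ± 0.87) and Adgra2 (−4.27 ± 0.54). The T-cell identity list had 3 of 25 genes positive (9 adjusted over the list alone, median 0.95; camera adjusted p 2.93e-13, and adjusted p = 0.011 with an estimated correlation). Tcf7 stood at 2.32 ± 0.47 (adjusted p 0.0503, and 1.43e-06 with series).

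Other lists in the test between phases were the Notch targets (median log2 1.46, 3 positive and 1 negative adjusted over the list alone; camera adjusted p 8.04e-05) and the erythroid, megakaryocyte and mast-cell genes (median −1.94, 2 negative in the list alone; camera adjusted p 8.04e-05). Stromal genes had a median of 2.27 (camera adjusted p 9.97e-06), B-cell and dendritic-cell genes 1.22 (2 positive in the list alone; 0.00585) and γδ and type 17 genes 0.91 (3 positive and 1 negative; 0.00452). Estimating the correlation gave these lists adjusted p-values of 0.254 to 0.503. Progenitor genes had a median of 0.41 and a mean of −0.38. With series, camera also called myeloid genes (adjusted p 0.0392) and NK and innate lymphoid genes (0.015) positive and p53 targets (0.0392) negative, and 1361 genes were called in all. The count was 3 to 369 without 1 of its libraries. For sgRunx1, 1 gene differed between phases (Poll, 1.39 ± 0.19, adjusted p 0.0463; 102 genes with series). For sgRunx3, edgeR called 0, with 92 at an unadjusted p under 0.05 and 0 with series.

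The called genes of the double target were also compared between phases over the 12938 genes tested in both. In both phases 36 genes rose, where independent lists would share 3.9 (odds ratio 13.5, 95% interval 8.8 to 20.3, Fisher's exact p 3.85e-25), and 39 fell, where they would share 2.56 (odds ratio 26.6, 17.2 to 40.9, exact p 3.11e-36). They included Cd3g (log2 −3.56 and −1.93), Lck (−2.72 and −0.87), Id2 (1.23 and 1.29) and Runx1 (0.86 and 0.94). A single gene, Arhgap23, chosen after its values were seen, rose in Phase 1 (1.26) and fell in Phase 2 (−0.41), and 0 did the reverse. The genes shared by both phases numbered 75 in the same direction and 1004 with series, where 41 rose in Phase 1 and fell in Phase 2 and 50 did the reverse (137 and 147 if independent).

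With no sgRunx3 calls, single targets could share none. Across genes, which are not independent replicates, the changes with sgRunx1 and sgRunx3 correlated at 0.524 in Phase 1 and 0.468 in Phase 2. Both used the same controls. In 20 simulations of unchanged groups against those controls, the mean correlation was 0.5 in Phase 1 and 0.503 in Phase 2 (highest 0.544 and 0.554). The shares of genes with the same sign were 71.2% and 71.9%, and 67.1% and 67.5% at most in the simulations. These held no library series, so they do not set the level that unchanged libraries paired by series would give. With series, 6 genes rose and 7 fell with both single targets in Phase 2, where independent lists would share 0.545 and 0.56, and part of that excess may come from the shared controls.

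In the Phase 1 double target, 4 of 1848 genes higher in DN2a rose and 56 fell (median log2 −0.13; camera adjusted p 2.56e-07), and 54 of 1718 genes higher in ETP rose and 10 fell (median 0.18; camera adjusted p 7.78e-05). With series these counts were 59 and 293, and 441 and 119. In the Phase 2 double target, 19 of 1850 genes higher in DN2a rose and 119 fell (median −0.05; camera adjusted p 4.19e-05). Of 1543 genes higher in ETP, 154 rose and 52 fell (median 0.16; camera adjusted p 4.7e-06), and with series the counts were 109 and 475, and 586 and 143. With sgRunx1 in Phase 2, 6 rose and 44 fell of the genes higher in DN2a (camera adjusted p 0.951), and 51 rose and 23 fell of those higher in ETP (camera adjusted p 0.0388, and 0.0756 with series). The difference between phases was not called for either list (camera adjusted p 0.328 and 0.596). None of these calls stayed with an estimated correlation (adjusted p 0.251 to 0.989). Limited to stage genes that changed at least 2-fold, the DN2a list lay lower with sgRunx1 in Phase 2 (median −0.2, camera adjusted p 1.58e-07, and 6.38e-05 with an estimated correlation) and in the double target of Phase 2 (−0.38, 1.84e-12, and 1.6e-05) and Phase 1 (−0.62, 3.46e-17, and 0.0506, or 0.0821 unadjusted with series). The ETP list so limited lay higher in the double target of Phase 1 (0.66, 4.11e-12, and 0.148) and Phase 2 (0.5, 2.5e-14, and 0.0966). The DN2a list then differed between phases (0.37, 2.88e-05, and 0.0286, but 0.0824 unadjusted with series and an estimated correlation), and the ETP list did not (0.06, 0.568, and 0.0335 by camera with series).

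The authors' Runx3 lists held 37436 peaks in Phase 1 and 36798 in Phase 2. Of these, 62.58% and 63.66% overlapped a peak of the other phase, leaving 14009 in Phase 1 only and 13371 in Phase 2 only. The odds of a promoter position were lower in Phase 1-only (odds ratio 0.214, 95% interval 0.201 to 0.228) and Phase 2-only peaks (0.272, 0.257 to 0.289) than in shared peaks, and lower in Phase 1-only than in Phase 2-only peaks (0.786, 0.729 to 0.847, Fisher's exact p 3.18e-10). With the stronger part of each list, the last 2 ratios were 0.497 and 0.407. Median distances to the nearest start were 8599, 19901 and 22091 bp for shared, Phase 1-only and Phase 2-only peaks. Their median tags were 27.5 (28.45 in Phase 2), 17.1 and 15.7, so class was not told apart from strength.

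**Figure D4:**
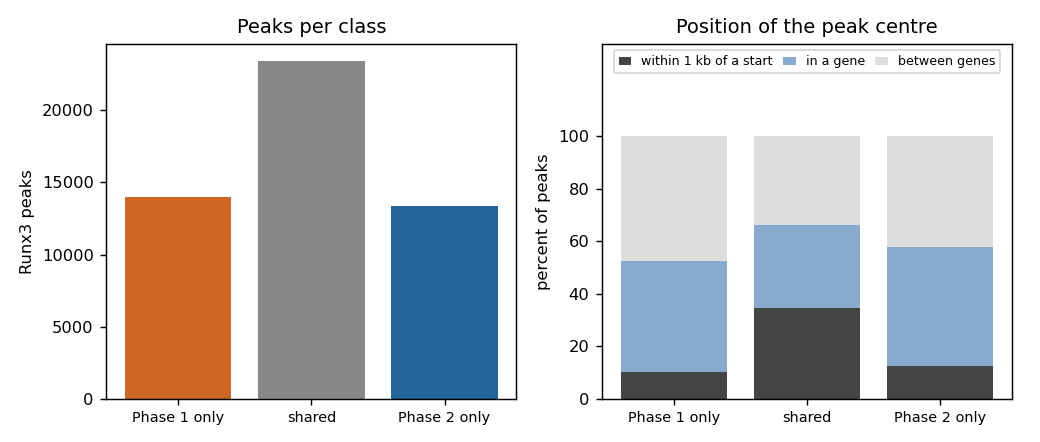
Number of Runx3 peaks per class (left, vertical axis) and the percent of each class whose centre lay within 1 kb of a gene start, in a gene or between genes (right, vertical axis). Shared peaks sat at promoters more often (34.46%) than Phase 1-only (10.12%) or Phase 2-only peaks (12.53%).

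At single loci, Bcl11b had 1 Phase 1-only, 5 Phase 2-only and 1 shared peak, and the strongest Phase 2-only peak lay in the gene (chromosome 12, 107993152 to 107993412; 37.9 tags). Cd3g had 1 peak, in Phase 2 only, at its promoter (chromosome 9, 44980354 to 44980614; 33.9 tags). Cd3d had 1 shared peak in its gene body (chromosome 9, 44986507 to 44986751; 218.9 tags in Phase 1 and 214.2 in Phase 2), and Cd3e had 4 Phase 2-only peaks and 1 shared peak. Tcf7 had 5 shared, 3 Phase 2-only and 1 Phase 1-only peak, with the strongest shared ones between genes (chromosome 11, 52318423 to 52318667 in Phase 1, 174.9 tags; 52314258 to 52314518 in Phase 2, 232.8 tags). Il2ra had 6 shared and 2 Phase 2-only peaks, the strongest between genes (chromosome 2, 11623192 to 11623436; 64.9 tags in Phase 1, 108.4 in Phase 2). Spi1 had 2 of each class. Runx1 had 6 Phase 1-only, 4 Phase 2-only and 6 shared peaks, the strongest at its promoter (chromosome 16, 92825879 to 92826123; 179.5 tags in Phase 1). Runx3 had 9, 5 and 11 in the same order, the strongest at its promoter (chromosome 4, 135120370 to 135120614; 241.6 tags in Phase 1, 220.6 in Phase 2). Meis1 had 4, 2 and 4.

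At the other fixed loci, Phase 1-only, Phase 2-only and shared peaks numbered 0, 1 and 4 at Gata3, 2, 5 and 3 at Ets1, 0, 0 and 1 at Rag1, and 1, 3 and 1 at Kit. They numbered 0, 2 and 1 at Lmo2, 2, 0 and 2 at Bcl11a, 2, 2 and 0 at Id2, 1, 1 and 8 at Zbtb16, 0, 0 and 1 at Mpo, and 0, 2 and 0 at Ptcra. The strongest Phase 1-only peaks began on chromosomes 3, 6 and 9 at 5860407, 3200825 and 123461872 (415.6, 291.1 and 250.1 tags). They lay 11.7, 8.4 and 8.0-fold over control (list median 18.46). The strongest Phase 2-only peaks began on chromosome 6 at 47739978, 47659422 and 103314528 (621.7, 492.8 and 488.7 tags). Their folds were 59.2, 38.6 and 4.3. Shared peaks beside the second held 492.8 tags too, so its class is uncertain. At Runx1 and Ets1 the strongest phase-only peaks of both phases nearly touch, so theirs is too.

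Genes that fell in the Phase 2 double target had Phase 2-only peaks more often than other genes: 216 of 318 (67.92%) against 38.61% of all 13465 genes (odds ratio 3.47, 95% interval 2.73 to 4.4, Fisher's exact adjusted p 2.22e-25). They also had Phase 1-only (2.07, adjusted p 7.14e-10) and shared peaks (2.18, adjusted p 6.48e-07) more often. Genes that rose in Phase 2 had more Phase 1-only (2.35, adjusted p 5.95e-16) and Phase 2-only peaks (1.94, adjusted p 5.6e-10), and their odds ratio for shared peaks was 1.06 (adjusted p 0.682), or 1.49 (adjusted p 0.00192) within deciles of mean expression. Genes that fell in Phase 1 had Phase 2-only (2.76, 1.86 to 4.09, adjusted p 6.48e-07), Phase 1-only (2.22, adjusted p 8.69e-05) and shared peaks (1.94, adjusted p 0.0133) more often. Genes that rose in Phase 1 had Phase 1-only peaks more often (1.81, 1.35 to 2.45, adjusted p 0.000168), a call lost within deciles of flank size, the distance between neighbouring starts (1.28, 0.937 to 1.75, adjusted p 0.134), and within 10 kb (1.25, adjusted p 0.24). They had shared peaks less often (0.562, 0.414 to 0.764, adjusted p 0.000399; 0.746 and adjusted p 0.0727 within deciles of mean expression). Shared peaks at genes that fell in Phase 1 lost the call within 10 kb (1.29, adjusted p 0.284). With the stronger part, they and Phase 2-only peaks at genes that rose in Phase 2 lost it (1.46 and 1.23, both adjusted p 0.074). At promoters alone, shared peaks were rarer at genes that fell in Phase 2 (0.62, adjusted p 8.19e-05) or Phase 1 (0.477, 0.000486) or rose in Phase 2 (0.533, 6.72e-09). Calls were lost there for Phase 1-only peaks at genes that fell in either phase or rose in Phase 1 (adjusted p 0.245 to 0.446), and for Phase 2-only peaks at genes that fell in Phase 1 (0.271) or rose in Phase 2 (0.142).

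**Figure D5:**
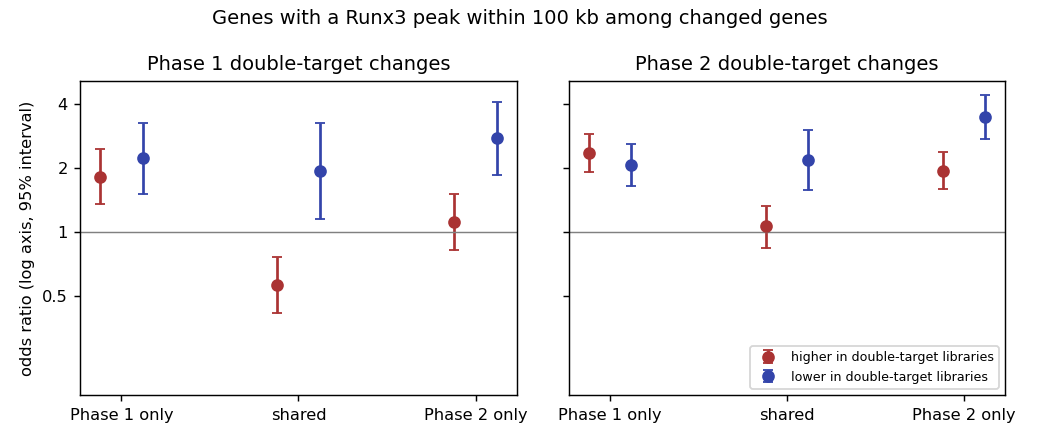
Odds ratio (log vertical axis, bars 95% interval) of carrying a Runx3 peak of each class (horizontal axis) for genes higher or lower in the double target of Phase 1 (left) and Phase 2 (right), against all other tested genes. The highest ratio was 3.47, for Phase 2-only peaks and genes that fell in Phase 2.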

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

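The tests with library series as a term and the test between phases for sgRunx1 were chosen after the result was seen; the other tests of this part were not.

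The double-target change differed between the phases, which also differ in sort gate, for 54 genes (Phase 2 minus Phase 1). Named genes with positive differences were Epas1 (log2 3.31), Cd5 (2.35), Rtn4rl1 (2.26), Arpp21 (2.13), Cd52 (2.04), Lck (1.81) and Cd3g (1.59). Negative ones were Shroom4 (−7.46), Grb10 (−5.53), Col18a1 (−4.81), Rab38 (−4.77), Adgra2 (−4.27) and Tal1 (−2.92). For sgRunx1 the change of 1 gene, Poll, differed between phases. No group held 4 to 10 samples, so no library was tested for lying far from the rest of its group.

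One pattern behind these differences was weighed. By list median, the double-target libraries of Phase 1 had lower T-cell identity genes and higher erythroid, megakaryocyte and mast-cell genes. One deviating library is argued against, since double-target replicate 2 over control replicate 2 had a median log2 ratio of −0.85 for T-cell genes and 0.92 for the other list (−0.96 and 1.99 in replicate 1). β-globin does not exclude red cells or their precursors: Hbb-b1 stood at −0.3 ± 0.12 in the fit with series, but the bound set for it was wrong, since its 331 and 385 CPM in the controls would hide a small share. The called list members had a median of 2.23 in that fit, with Gata1 at 2.73, Epor at 2.84 and Klf1 at 2.43. Red-cell, megakaryocyte or mast-cell precursors passing the lineage-negative, cKit-high gate, and a redirection of the perturbed cells, may each account for the pattern and stay open. The count with library series as a term (2478 against 281) decides nothing about a batch, as the term cannot remove a difference between groups.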

How the results depend on the processing

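Library series as a term, the fit without the Phase 1 double-target libraries and the replicate block under stage lists were chosen after the data were seen. So were the peak overlap on numbered chromosomes or of the stronger part of 1 list against the whole other list, peak tests by flank size, the split of simulations by level and the phase tests of single targets. The others were planned. Where a moved value has no cause given, none was tested.

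DESeq2 called 33 (sgRunx1), 4 (sgRunx3) and 1160 (double target) genes in Phase 1, 406 and 702 for the double target against sgRunx1 and sgRunx3 there, and 5 between single targets. In Phase 2 it called 639, 2, 1181, 119, 1016 and 402 in the same order. It called 292 for the difference between phases, with 314 genes shared by both phases. With a change of at least 2-fold required, which can only remove calls, 1070 remained for DN2a against ETP, 1320 for Bcl11b-positive DN2a, and 156 (sgRunx1), 447 (double), 339 (double against sgRunx3) and 79 (between single targets) in Phase 2. Fitting only the groups compared, which leaves fewer libraries for the spread, gave 0 for the Phase 1 double target against control and against sgRunx3, and 114, 359, 0, 218 and 34 for sgRunx1, double, double against sgRunx1, double against sgRunx3 and between single targets in Phase 2. No low-count filter gave 125 for the Phase 1 double target against sgRunx3. DESeq2 size factors gave 6 and limma on RPKM plus 1 gave 36 for the Phase 2 double target against sgRunx1, and limma on RPKM plus 0.1 gave 2577 for Bcl11b-positive DN2a; these settings and the stricter filter left the other counts they were run on within 1.5 times.

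With the replicate number as a block, the calls were 2478, 1187 and 1935 for the Phase 1 double target against control, sgRunx1 and sgRunx3, 697, 1486, 175, 1219 and 474 for the 5 Phase 2 comparisons in the order above, and 627 between phases; of the named genes 57 gained and 1 lost the call, and it moved no other count past 1.5 times. In the stage table the numbers were not shown to pair the libraries (correlations of 0.55 over 2 pairs); there the block gave 5196 and 5689 calls and Bcl11b an adjusted p of 9.92e-08. Library series as a term gave 2478, 1187 and 1935 in Phase 1, and 1991, 15 (sgRunx3), 3490, 2049, 4350 and 1363 in Phase 2. It gave 1361 between phases, 102 for sgRunx1 between phases, 1004 genes shared by both phases and 13 shared by the single targets of Phase 2. Without the double-target libraries, it gave 1120, 763 and 651 for the Phase 1 single targets and between them. Single-replicate omissions gave 1738 to 2184 calls for Bcl11b-positive DN2a, 1491 to 2609 for DN2a against ETP, 0 to 1158, 0 to 590 and 0 to 903 for the Phase 1 double target against control, sgRunx1 and sgRunx3, and 0 for the Phase 1 single targets and between them in every omission. In Phase 2 they gave 98 to 167, 0 in every omission, 370 to 490, 0 to 4, 243 to 332 and 23 to 80 in the order sgRunx1, sgRunx3, double, double against each, and between single targets, and 3 to 369 between phases; a lone library was assumed to vary like the other groups.

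Groups by the gate in the labels gave 0 calls for DN2a against ETP and no stage lists, and turned the sign of 29 named genes, since that grouping mixes both stages in each group. Their log2 values there, all at an adjusted p of 1, were Fcrla 1.26, Fcer1a 1.06, Cplx2 1.49, Ms4a2 0.16, Lmo2 0.14, Bcl11a 0.07, Cd6 0.21, Itgam 0.13, Csf2rb 0.09, Tyrobp 0.22, Pax5 0.73, Tcf4 0.05, Blnk 1.14, Il1r1 0.04, Maf 0.6, Cbfa2t3 0.13, Ccne1 −0.1, Top2a 0.04, Mcm6 −0.05, Mcm4 −0.12, Aen −0.04, Pmaip1 0.27, Bbc3 0.27, Ccr7 0.55, Mcpt8 0.03, Pdgfrb 0.32, Zfp36 0.04, Ier2 −0.17 and Kit −0.05. With 1 library against 1 on which title and gate agree, 58 of 58 named genes kept their sign. Over all settings, single named genes gave 5314 values on the same side of the threshold and with the same sign, 594 that lost the call, 244 that gained it and 29 that turned.

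With an estimated correlation, 2 of 92 list calls and 0 of 22 stage-list calls stayed, but 8 of 22 did with stage genes changed at least 2-fold, all 8 for the list higher in DN2a. Of the list tests, fry called 14. Peak overlap in Phase 1 and Phase 2 was 58.43% and 59.45% with reciprocal overlap of 50%, 56.21% and 57.18% for centres within 100 bp, 62.04% and 63.1% for the stronger part of both lists, and 78.43% and 81.23% for the stronger part of 1 list against the whole other list. Of the peak classes tested against expression, 10 of 12 were called, and 6 with promoter peaks alone. Odds ratios turned for shared peaks and genes that rose in Phase 2 within 10 kb (0.794), and at promoters for shared peaks and genes that fell in Phase 1 (0.477), rose in Phase 2 (0.533) or fell in Phase 2 (0.62). With 1 list per phase, peaks allowed no paired analysis. The motif window around peaks was not run as no genome was used. In simulations, fewer of the genes changed by log2 1 were called in the lower than in the upper part of the levels, at 14.3% and 31.4% for sgRunx1 in Phase 1 (parted at 45.4 CPM) and 51% and 77.6% in Phase 2 (44 CPM); depth was not told apart from the spread between libraries.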

Other observations

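The tests of peaks within deciles of flank size, of fallen against risen genes and of Runx3 peaks at Runx1, the splits with library series, and the bound for the planned deciles of expression were chosen after the results were seen; the other tests of this part were not.

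Runx1 mRNA was higher with Runx1 guides in Phase 2. Scaling is argued against, as the lowest log2 change over the other scalings was 0.72. A change of the whole region is argued against, as the 8 other tested genes within 1 Mb had a median of 0.11 (−0.16 to 0.28). A release of the gene from its own protein may be the cause; 6 shared Runx3 peaks at Runx1 leave room for it, but neither RUNX1 protein nor the guide sites were measured here, so this stays open.

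Phase 2-only peaks lay near genes that fell in the Phase 2 double target. Large flanks between gene starts, which collect peaks, are argued against by an odds ratio of 3.53 (95% interval 2.7 to 4.62, 13449 genes) within deciles of flank size, and expression level by 3.28 (2.58 to 4.16) within its deciles. Fallen genes had such peaks more often than risen genes (odds ratio 1.77, 1.29 to 2.44, Fisher's exact p 0.000285). So had they for shared peaks (2.04, 1.36 to 3.1), and Phase 2-only peaks showed it in Phase 1 as well (2.47, 1.46 to 4.19), whereas for Phase 1-only peaks the ratio was 0.886 (0.65 to 1.21) in Phase 2 and 1.22 (0.731 to 2.05) in Phase 1. Whether sites called in Phase 2 only act on these genes stays open. Distal sites can act on other genes, which was not tested.

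The 6 libraries of each comparison of 3 against 3 in Phase 2 can be split in 10 ways, which are too few for a share under 0.05. For sgRunx1 against control the real split called 249 genes and the highest other split 0, so 1 of 10 reached it. For sgRunx3 against control the real split and all others called 0, so 10 of 10 did; with library series as a term the real split called 15 and the highest other split 0. For sgRunx1 against sgRunx3 the real split called 122 and the highest other split 0, so again 1 of 10 reached it. With series these real splits called 1991 and 1363, and the highest others 0.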
